A study of Homo sapiens with 8 samples.

How the data were processed

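NKRF was immunoprecipitated with an antibody from MDA-MB-231-P3 cells transfected with a control siRNA or with siRNA against Uc003xsl.1, and the immunoprecipitated and input DNA were sequenced, per the labels' protocols. Cells were fixed in 1% formaldehyde for 10 min, quenched with 125 mM glycine and sheared to fragments of 100 to 500 bp, and libraries were amplified for 15 cycles and selected at about 250 bp, per the labels' protocols. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that replicates came from separate cultures. Permutation p-values over splits of the libraries therefore measure only the spread between these libraries, which may be technical. The tests of gene lists, shared genes and placements count genes or peaks within 1 list, region set or pair of lists. Their p-values do not measure the spread between libraries. The 4 input libraries and the IgG control were not analysed here beyond the input totals in the headers.

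Reads were aligned with Bowtie2 to GRCh38.p11, with CASAVA 1.4 also named, per the submitters' processing notes; the alignment settings were not given in the sources used here. Peaks were called per library, each against 1 input library and not on pooled replicates, per the file headers. Control replicate 1 and both si-Uc003xsl.1 libraries were called with MACS 1.4.2 at a p-value threshold of 1e-04 with 50-bp tags, a band width of 200 bp and an effective genome size of 3.21e+09, per the file headers. Control replicate 2 was called with MACS 2.1.1.20160309 at a q-value threshold of 0.05 with 105-bp tags, a fixed extension of 150 bp and an effective genome size of 3.09e+09, per the file headers. In both programs 1 tag was kept per position, per the file headers. All peaks of control replicate 2 lie on chromosomes 1 to 22 and X, while the other 3 lists also hold peaks on scaffolds. A stricter threshold, longer tags and fewer tags can each shorten a list, so peak numbers of control replicate 2 are not comparable with the others.

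The MACS 1.4.2 lists give the count of tags in each peak, deposited without normalization. They give a score of -10 times log10 of the p-value, per the file headers. The fold enrichment over input is the authors' ratio, with the larger dataset scaled to the smaller, per the file headers. The false discovery rate is a percent that the authors' caller estimated for each peak, per the file headers. For control replicate 2 the deposited values are the pileup signal at the summit, the fold enrichment, and -log10 of the p-value and of the q-value, per the file headers. Scores, folds and tag numbers per peak are the authors' values and were used only to describe, rank or filter peaks. They were not rescaled between lists. Where tag counts or tag classes of several lists are set side by side, differences in depth may therefore contribute. Medians of fold enrichment were 12.0, 5.43, 10.2 and 10.4 in control replicates 1 and 2 and si-Uc003xsl.1 replicates 1 and 2, and they describe each list alone.

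Filtered NKRF tags numbered 19335431, 8250475, 18890698 and 11366267 in the same order, and filtered input tags 19363334, 11886717, 19221589 and 19541097. Shares of peaks carry exact Clopper-Pearson 95% intervals, which cover counting error only.

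Coordinates are the authors' own, 1-based, on GRCh38. Gene names came from a RefSeq table of 59792 genes, 20056 of them protein-coding, on GRCh38.p14. Patch releases keep the coordinates of the primary chromosomes, so the table was used to find which genes neighbour a peak, and no gene coordinate of it is printed. The table gives neither strand nor exons. Shares near transcription start sites were therefore computed as shares within 1 kb of either end of a gene, and exons and introns were merged into gene bodies. List tests used a window of 10 kb around either end. This departs from the plan, which named transcription start sites.

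Peaks were shared when they overlapped by at least 1 bp. Peaks of all lists that touched were merged into regions, which were counted by the libraries holding them. Each list was compared with 100 placements at random positions of the same chromosome, gaps included, and, chosen after seeing the data, with 100 local placements shifted by 20 to 200 kb either way. Group differences of single values were tested by exact two-sided permutation over the 3 splits of 4 libraries into pairs. The 9 gene lists were fixed before the data were examined and all their members matched a gene. They were tested in the 4 libraries and 2 region sets by Fisher's exact test with Benjamini-Hochberg adjustment over 54 tests, and against 10000 random lists matched on gene length. Named genes followed a rule written in advance: CXCL8 and NKRF, the 10 regions of each kind with the highest mean percentile of -log10 p within their lists, named by the protein-coding gene containing the summit or else the nearest one, and list members within 10 kb of such a region, at most 5 per list. Genes with a peak in the list tests and in the chemokine cluster on chromosome 4 were named after their values were seen, and 1 member of the interferon list is not reported here by name.

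Overlap, list and gene-end computations were tested on simulated peak lists. With 150 regions planted in the si-Uc003xsl.1 pair 151 were counted, 25 of 25 planted in the control pair and 40 of 40 planted in all lists were recovered, and 541 of 576 planted gene-end peaks were found as excess in si-Uc003xsl.1 replicate 1. Alternatives were other overlap rules, stronger parts of the lists, equal list lengths, chromosomes 1 to 22 and X, other windows, the replicate number as a block, and leaving out each library. The planned searches for DNA motifs and repeats need a genome sequence and were not run. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, with random seed 20240501.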

Results

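Chromatin immunoprecipitation followed by sequencing (ChIP-seq) measured where NKRF, the NF-kB repressing factor, was bound to DNA in MDA-MB-231-P3 cells, a highly metastatic subline of the triple-negative breast cancer line MDA-MB-231. Cells had received either a control siRNA or an siRNA against the long non-coding RNA Uc003xsl.1 (si-Uc003xsl.1). The series title names this RNA as a decoy for NKRF that acts on NF-kB and IL8, so the comparison asks whether NKRF binding differed after the siRNA against it. The level of the RNA was not measured in the data used here. There were 2 NKRF libraries and 2 input libraries per condition, and 1 peak list per NKRF library was used. After duplicate filtering the NKRF libraries held 19335431 tags (control replicate 1), 8250475 (control replicate 2), 18890698 (si-Uc003xsl.1 replicate 1) and 11366267 (si-Uc003xsl.1 replicate 2). Control replicate 2 was called with another program version, threshold and tag length than the other 3 lists, so in the control group the replicate and the processing cannot be told apart.

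NKRF peaks after si-Uc003xsl.1 included broad regions, whereas the control lists held none as wide as 500 bp. In si-Uc003xsl.1 replicate 1, 714 of 7577 peaks (9.42%) reached that width, and in replicate 2 it was 489 of 4463 (10.96%). The widest peak measured 458 bp and 382 bp in the control libraries against 2559 bp and 2952 bp after si-Uc003xsl.1. The fragment length that the caller used also differed, at 49 bp and 150 bp in control replicates 1 and 2 and 60 bp and 67 bp after si-Uc003xsl.1. Its effect on peak width was not tested. Control replicate 1 had 7444 peaks with a median of 6 tags, and 5067 of them (68.1%) sat at 6 tags, the smallest count in that list. The corresponding shares were 31.9% and 33.1% in the si-Uc003xsl.1 libraries. Every peak of control replicate 1 carried a false discovery rate of 100% from the caller, against medians of 30.8% and 10.96% after si-Uc003xsl.1, where 0 and 5 peaks lay at or below 5%. Of these 5, 4 were mitochondrial and 1 lay on chromosome 3 at 93470345 to 93470816, 402345 bp from the nearest protein-coding gene end. Control replicate 2 had 902 peaks. The mean peak number was 4173 ± 4626 (SD, n = 2) in controls and 6020 ± 2202 (SD, n = 2) after si-Uc003xsl.1. The log2 difference of 1.17 did not exceed the spread between replicates (two-sided exact permutation p = 0.667, where 0.333 is the smallest p that the 3 splits allow). Among the lists from the shared program it had the other sign, with -0.36 without control replicate 2 against 2.69 without control replicate 1.

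**Figure D1:**
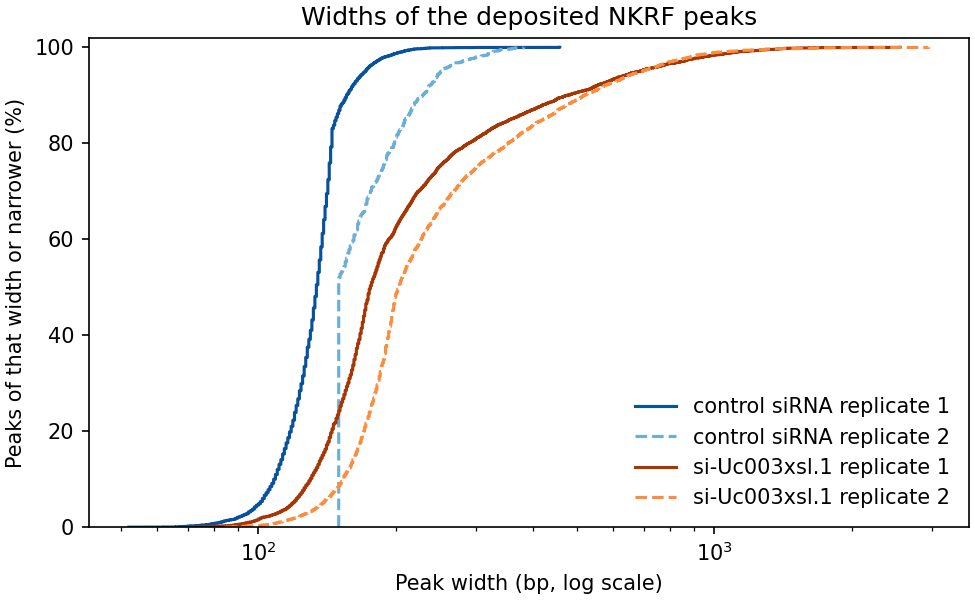
Cumulative distribution of peak width for the 4 NKRF libraries, with width in bp on a log axis and the percent of peaks of that width or narrower on the vertical axis. Both si-Uc003xsl.1 curves reach beyond 500 bp, while the control curves end at 458 bp and 382 bp.

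Genomic regions called in more than 1 NKRF library were few, and nearly all of them belonged to the si-Uc003xsl.1 pair. The 4 lists merged into 20208 regions, of which 20035 (99.1%) occurred in a single library. Both si-Uc003xsl.1 libraries and neither control held 155 regions, with a median width of 676 bp. Of these, 94 (60.6%, exact Clopper-Pearson 95% interval 52.5 to 68.4) lay within 1 kb of an end of a protein-coding gene. Both control libraries and neither si-Uc003xsl.1 library held 1 region, and 0 regions occurred in all 4. The other splits of the libraries gave 11 against 1 and 4 against 1 regions. With the top 902 peaks of every list, 18 regions were called in the si-Uc003xsl.1 pair alone, and with a reciprocal overlap of 50% it was 101.

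Peak by peak, 156 of the 4463 peaks of si-Uc003xsl.1 replicate 2 overlapped a peak of replicate 1 (3.50%, interval 2.98 to 4.08). Random placement on the same chromosomes gave a mean of 6.84 overlaps and at most 14 in 100 placements. Shifting each peak by 20 to 200 kb gave a mean of 10.97 and at most 22 (one-sided permutation p = 0.0099, the smallest that 100 placements can give). Shifted peaks of replicate 2 lay near gene ends in 4.13%, against 21.98% of the called ones. Lists that both favour gene ends could therefore also exceed these placements. In the other 5 pairs the overlap stayed within the range of both kinds of placement. Control replicate 1 shared 11 of its 7444 peaks with si-Uc003xsl.1 replicate 1 (0.148%, interval 0.0738 to 0.264) and 4 of 4463 with replicate 2 (0.0896%). The 2 control lists shared 1 of 902. Within-group overlap exceeded between-group overlap by 1.69 percentage points, against -0.82 in the higher of the other splits (exact permutation p = 0.333, the smallest possible with 2 libraries per group). This excess came from the si-Uc003xsl.1 pair: it was 0.0106 without si-Uc003xsl.1 replicate 1 and -0.0185 without replicate 2.

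**Figure D2:**
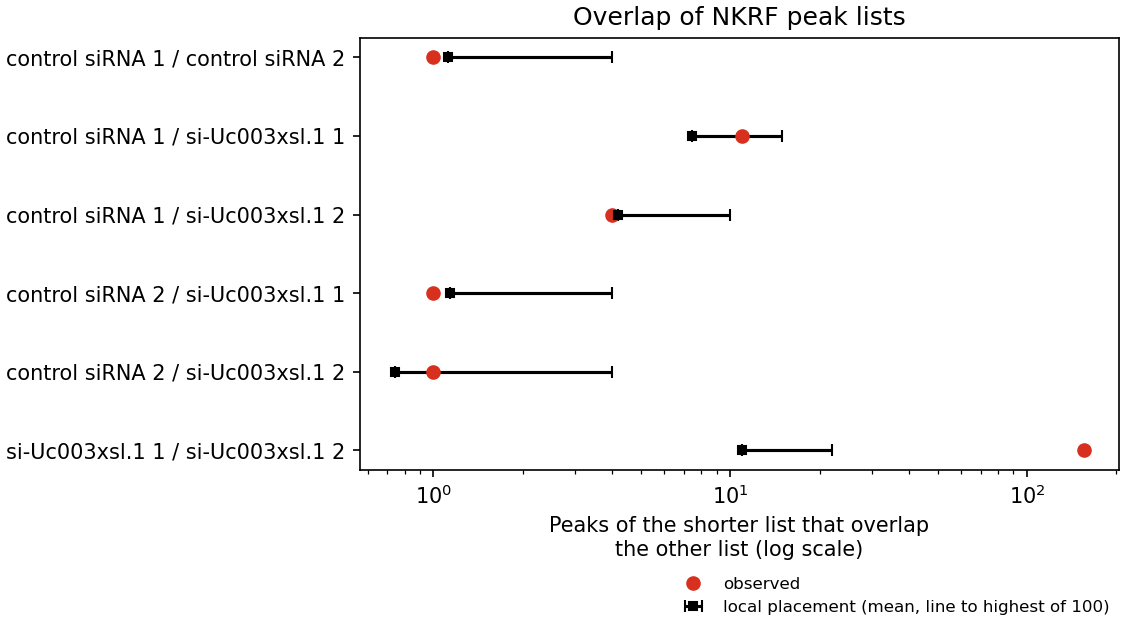
Number of peaks of the shorter list that overlap the other list, on a log axis, for the 6 pairs of NKRF libraries. Red points are observed counts and black squares are means of 100 local placements with a line to the highest. The si-Uc003xsl.1 pair, at 156, lies above its highest placement of 22. These placements did not keep the share of peaks near gene ends.

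The 10 regions ranked highest within the si-Uc003xsl.1 lists lay mostly at ends of genes of varied function. The region at CTSF, which encodes the lysosomal protease cathepsin F, spanned 66567987 to 66568657 on chromosome 11, with its summit 97 bp inside a gene end, and held 40 and 22 tags in replicates 1 and 2. At DGKZ, a diacylglycerol kinase gene, the region at 46332514 to 46333416 on chromosome 11 held 41 and 24 tags, 339 bp outside the gene. At IGF2BP2, which encodes an mRNA-binding protein, the region at 185824337 to 185826620 on chromosome 3 was 2284 bp wide and held 82 and 101 tags, 98 bp outside the gene. ST6GALNAC6, a sialyltransferase gene, contained a region at 127898537 to 127899798 on chromosome 9 with 77 and 37 tags, 7143 bp from the nearest gene end. The others were at ZDHHC2, CAMSAP1, MYO3A, SLC4A7, SRRM3 and MTCL2. CAMSAP1 and MTCL2 encode microtubule-associated proteins, and SLC4A7 a bicarbonate cotransporter. SLC4A7 had 40 tags in each library at 27483769 to 27484699 on chromosome 3, and MTCL2 had 79 and 46 tags at 36863171 to 36864452 on chromosome 20, 24 bp outside the gene. The caller's false discovery rate in these 10 regions ranged from 15.7% at SLC4A7 to 43.2% at SRRM3, both in replicate 2, so none reached 5% in either library. A higher rate did not mean a weaker peak, since -log10 p there was 5.96 at SLC4A7 and 8.64 at SRRM3. Under a reciprocal overlap of 50%, the regions at DGKZ, IGF2BP2 and ST6GALNAC6 no longer counted as shared, and with equal lists of 902 peaks the region at SRRM3 did not.

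From the gene lists fixed in advance, TGFB1 and RPLP0 had a region of the si-Uc003xsl.1 pair within 10 kb. They were 1 of 26 epithelial-mesenchymal transition and invasion genes and 1 of 25 housekeeping genes, against 0.84% of other genes in both tests. Fisher's exact test gave unadjusted p = 0.198 and p = 0.191, so neither list passed. The other lists had no such member. TGFB1, which encodes the cytokine transforming growth factor beta 1, contained the region at 41352635 to 41354240 on chromosome 19, with its summit 507 bp from a gene end and 60 and 41 tags. The region nearest RPLP0, a ribosomal protein gene, lay at 120194339 to 120195031 on chromosome 12, 1947 bp outside the gene, with 46 and 40 tags. Its summit was closer to another gene, GCN1, 37 bp outside an end of it. Neither region was shared once each list was reduced to its stronger part or to 902 peaks, and under a reciprocal overlap of 50% that at TGFB1 was not. The single region of the control pair, at 58895422 to 58895713 on chromosome 14, had no protein-coding gene nearby, the nearest being DACT1 at 247156 bp. It held 6 tags in control replicate 1 and a pileup of 8 in control replicate 2.

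Ends of protein-coding genes, which include their transcription start sites, carried a far larger share of the called peaks after si-Uc003xsl.1 than in controls. Within 1 kb of a gene end lay 1210 of 7577 peaks (16.0%, exact Clopper-Pearson interval 15.2 to 16.8) in replicate 1 and 981 of 4463 (21.98%, interval 20.8 to 23.2) in replicate 2, 5 of the latter on the mitochondrial chromosome. In controls it was 101 of 7444 (1.36%, interval 1.11 to 1.65) and 23 of 902 (2.55%, interval 1.62 to 3.80). Local placement gave 3.43% and 4.13% for the si-Uc003xsl.1 lists and 1.75% and 2.45% for the control lists. Control replicate 1 lay below the lowest of its 100 placements (1.402%). Every peak of that list carried a false discovery rate of 100%, and only 112 had 10 or more tags, against 2423 and 1658 after si-Uc003xsl.1. Of these 112, 3.57% lay near gene ends, within the range of local placements. Low enrichment in that library therefore cannot be told apart from a change in NKRF binding. Peaks near gene ends were wide after si-Uc003xsl.1, with medians of 430 bp and 393 bp against 170 bp and 194 bp elsewhere, and had medians of 24 and 19 tags against 7 and 7. Intergenic sequence held 40.8% and 38.0% of control peaks against 31.3% and 24.8% after si-Uc003xsl.1, and gene bodies held 43.4%, 46.2%, 40.5% and 43.6% in the same order of libraries.

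The mean share near gene ends was 1.95% ± 0.84 (SD, n = 2) in controls and 19.0% ± 4.25 (SD, n = 2) after si-Uc003xsl.1. The difference of 17.0 percentage points exceeded the spread between replicates, and both si-Uc003xsl.1 libraries lay above both controls (two-sided exact permutation p = 0.333, the smallest that 2 libraries per group allow, so the test cannot reach 0.05). Among the 3 lists from the same program version the difference was 17.6 points, with 1 control library and hence no test. With 902 peaks per list it was 31.7 points.

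**Figure D3:**
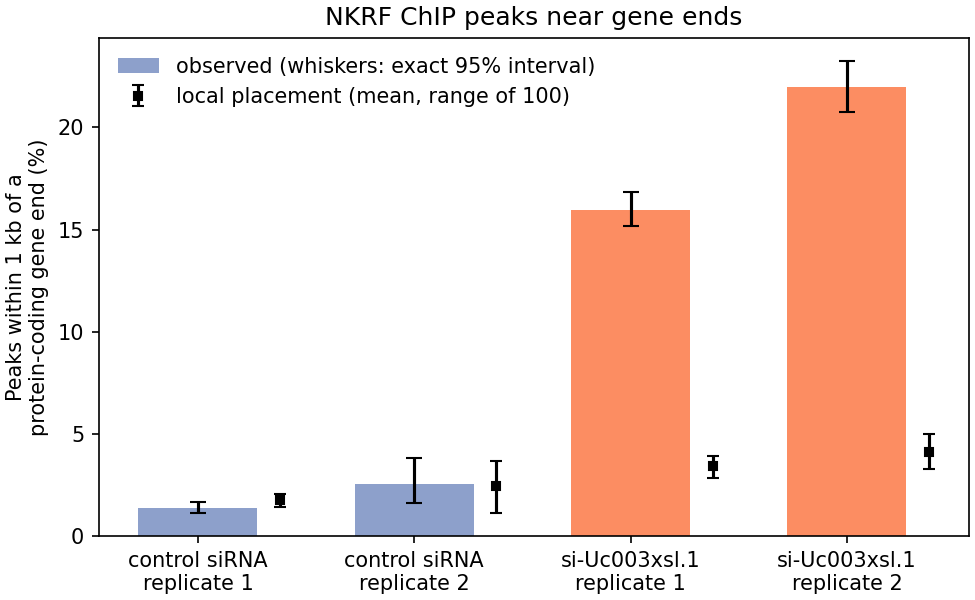
Percent of NKRF peaks with a summit within 1 kb of an end of a protein-coding gene, for each library (bars from 0, whiskers: exact 95% interval), beside the mean and range of 100 local placements (black squares). The control libraries stand at 1.36% and 2.55% and the si-Uc003xsl.1 libraries at 16.0% and 21.98%, the latter pair above all their placements.

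More genes carried gene-end peaks in both si-Uc003xsl.1 libraries than lists drawn evenly from all protein-coding genes would give. Of 20056 protein-coding genes, 1311 had such a peak in replicate 1 and 1065 in replicate 2, and 133 had one in both against 69.6 for independent lists (odds ratio 2.16, Fisher's exact test adjusted p = 1.66e-12 over the 6 pairs of libraries). This test compares these libraries, and neighbouring genes are not independent. It takes every gene as equally likely to carry a peak. A preference of both lists for the same class of genes would also raise the shared number, and this was not tested. Control replicate 1 had 106 such genes and shared 6 with si-Uc003xsl.1 replicate 1 against 6.93 for independent lists, and 7 with replicate 2 against 5.63 (Fisher's exact test, both adjusted p = 1).

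Of the 9 gene lists, olfactory receptor genes, chosen as genes with no expected activity in breast cancer cells, were the one that passed the test with windows of 10 kb. Within 10 kb of their ends, 13 of 392 (3.32%) had a peak in si-Uc003xsl.1 replicate 1 against 16.3% of other genes (odds ratio 0.18, Fisher's exact test with Benjamini-Hochberg adjusted p = 4.76e-14), and 7 of 392 (1.79%) in replicate 2 against 12.9% (odds ratio 0.12, adjusted p = 9.93e-14). Random lists matched on gene length gave an adjusted p of 0.0108 for peaks in the gene body in both libraries. In controls 25 of 392 (6.38% against 4.96%) and 5 of 392 (1.28% against 1.03%) had a peak, with adjusted p = 1 by Fisher's exact test in both, and the difference between the groups was not tested. With 902 peaks per list the call in replicate 2 was lost (odds ratio 0.25, Fisher's exact adjusted p = 0.134). Receptor genes lie in clusters, so they are not independent of each other.

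NF-kB target genes carried peaks near their ends at shares close to those of other genes in the si-Uc003xsl.1 libraries. In si-Uc003xsl.1 replicate 1, 8 of 52 (15.4%) had a peak within 10 kb of an end against 16.0% of other genes: IKBKE, CCND1, NFKBIB, CXCL6, CXCL5, NFKB1, CSF2 and IRF1. In replicate 2 it was 7 of 52 (13.5% against 12.7%): IL1B, CXCL5, CD83, VEGFA, NFKBIE, IL6 and TRAF2. For peaks in the gene body, random lists matched on length gave 3 members against 4.24 expected in replicate 1 (permutation p = 0.749, adjusted p = 1) and 8 against 3.44 in replicate 2 (permutation p = 0.035, adjusted p = 0.63). Control replicate 1 had a peak at 1 of 52, NFKBIZ, and control replicate 2 at 0. Fisher's exact test gave an adjusted p of 1 in each library. None of the 3 genes described as NKRF targets, CXCL8, IFNB1 and NOS2, had a peak within 10 kb in any library.

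Among 26 genes of epithelial-mesenchymal transition and invasion, control replicate 1 had peaks at ITGB1, CD44, MMP1, CDH2 and LOX (Fisher's exact p = 0.00837, adjusted p = 0.151). Si-Uc003xsl.1 replicate 2 had them at MMP14, CDH2, AXL, TGFB1, PLAUR, SNAI2 and TNC (Fisher's exact p = 0.0387, adjusted p = 0.522), and replicate 1 at ITGA5, MMP14, ITGB3, CDH2 and TGFB1. Of 30 interferon genes, 4 had a peak within 10 kb in control replicate 1 (Fisher's exact adjusted p = 0.649), but with windows of 50 kb it was 15 of 30 (odds ratio 4.60, Fisher's exact adjusted p = 0.00111), and several of these genes are neighbours. Within 10 kb there were 7 in si-Uc003xsl.1 replicate 1, among them MX1, and 2 in replicate 2, IFIT1 and IFNL2. Of 30 ribosome biogenesis genes the counts were 2, 4 and 3 in the same 3 libraries, of 30 cell cycle genes 1, 5 and 4, of 21 breast epithelial markers 3, 4 and 2, and of 25 housekeeping genes 1, 3 and 5. Control replicate 2 had a peak at 1 gene of these lists, ENO1. In all, 2 of 54 list tests passed an adjusted p of 0.05, both for olfactory receptor genes, and 4 passed an unadjusted p of 0.05.

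CXCL8, the gene of the chemokine IL8 on chromosome 4, had no NKRF peak within 10 kb in any of the 4 libraries. The nearest peak lay 11.5 kb away in si-Uc003xsl.1 replicate 1, at 73755142 to 73755295 with 7 tags and a false discovery rate of 30.8%. In the other libraries the nearest was at 297 kb (control replicate 1), 81.2 kb (control replicate 2) and 238 kb (si-Uc003xsl.1 replicate 2). At other chemokine genes of this cluster, a peak of si-Uc003xsl.1 replicate 1 lay 172 bp inside an end of CXCL6, at 73836650 to 73836969 with 13 tags. Peaks of replicate 2 lay inside PF4 and CXCL5, with 12 and 8 tags. CXCL5 also had a peak of replicate 1 within 10 kb, at 73991535 to 73991725 with 8 tags, which did not overlap that of replicate 2 at 73996104 to 73996286. NKRF itself, on chromosome X, had no peak within 100 kb in any library, the nearest being 105497 bp away in si-Uc003xsl.1 replicate 1. A list of called peaks does not show signal below the caller's threshold, so at this depth binding at CXCL8 was not detected, which is not evidence of absence.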

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

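The comparison of mitochondrial peaks was chosen after the result was seen. Si-Uc003xsl.1 replicate 2 had 6 peaks on the mitochondrial chromosome, 5 of them within 1 kb of a gene end there, while control replicate 1 and si-Uc003xsl.1 replicate 1 had 0. The list of control replicate 2 held no peak outside chromosomes 1 to 22 and X. Whether mitochondrial sequence was searched in it is not known, so its 0 was not interpreted. The strongest of the 6, at 1218 to 4169, held 3630 tags with the authors' fold of 1.91 and a false discovery rate of 0%. No explanation was tested for this.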

How the results depend on the processing

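Chosen after seeing the data were local placement, the removal of peaks at the smallest tag count, and all alternatives for genomic classes and for overlap beyond chance. The difference in the share near gene ends kept its direction under every alternative run, from 14.0 to 31.7 percentage points. Regions of the si-Uc003xsl.1 pair alone numbered 155, against 101 with a reciprocal overlap of 50%, 69 in the stronger part of each list and 18 in equal lists of 902 peaks, where fewer peaks entered the last 2. Regions of the control pair alone numbered 1, against 3 within 500 bp and 0 with reciprocal overlap, the stronger part, equal lists or no peaks at the smallest tag count. Overlap of the si-Uc003xsl.1 pair was 22.8 times that of random placement, 42.1 times in the stronger part and 11.01 times within 500 bp; it was 14.1 times that of local placement in a second draw of 100 (14.2 in the first), and the cause was not tested. List tests past the threshold numbered 2, against 4 with 50 kb windows (interferon genes in control replicate 1, and olfactory receptor genes in both si-Uc003xsl.1 libraries and the regions they share) and 1 with equal lists. Leaving out single libraries moved the log2 peak number difference between -0.36 and 2.69, within-group minus between-group overlap between -0.0185 and 3.38 points, and, as 1 library then defines a side, si-only regions between 155 and 7565 and control-only regions between 1 and 7429. Of 12 named regions, 8 held with reciprocal overlap, 10 in the stronger part and 9 in equal lists.

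In the sample titles, same-numbered libraries share only a number. The difference of replicate 1 and replicate 2 in log2 peaks per bin correlated at 0.093 between the groups over 619 bins of 5 Mb. In controls that difference is also one of program and threshold, so it cannot show whether same-numbered libraries share a batch. With the replicate number as a block, the gene-end odds ratio was 13.0 against 14.8 pooled, the peak number difference stayed at 1.17 (exact sign-flip p = 0.5, the smallest possible), and same-numbered pairs of the 2 groups overlapped 0.0291 points more than others. Motif and repeat alternatives were not run. Depth limits control replicate 2 most, with 8250475 tags.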

Other observations

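Chosen only after the result was seen were the tests of placement, list length, caller, enrichment and NKRF binding for the shared regions, the test of depth for gene ends, the comparison of tag classes, the restriction to 582 bins, the restriction of tRNA genes to chromosomes with its counting limits, and the choice of gene types and of the strongest peaks named.

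Of 6 non-coding gene types, lncRNA genes alone carried more NKRF peaks at their ends than every local placement in both si-Uc003xsl.1 libraries. Within 1 kb of an lncRNA gene end lay 483 peaks of replicate 1 against a mean of 212 in local placements, and 373 of replicate 2 against 134. Both exceeded the highest placement (249 and 159). Peaks that also lay within 1 kb of a protein-coding gene end were not removed, so the lncRNA excess may repeat that at protein-coding genes. At microRNA gene ends replicate 1 had 37 peaks against 12.7, above the highest placement of 24, and replicate 2 had 16, equal to its highest. Pseudogene ends had 121 and 92 peaks in replicates 1 and 2 (highest placements 137 and 92), snoRNA ends 9 and 2 (14 and 11), snRNA ends 1 and 1 (3 and 3) and tRNA ends 7 and 2 (7 and 5). The control libraries had 163 and 25 peaks at lncRNA ends against means of 161 and 22.4. The strongest peaks of si-Uc003xsl.1 replicate 1 on the authors' scale lay at HPCAL1, 6 bp outside a gene end with 95 tags, and inside CCDC88C with 71 tags. Their false discovery rates were 100% and 50%, and the rate fell with each rank to 10% at the peak ranked 10. The 100% at the top of this list is therefore unlike that of control replicate 1, where every peak carried it. In replicate 2 the 6 strongest were 4 mitochondrial peaks, the peak on chromosome 3 at 93470345 to 93470816 with 748 tags, and 1 on a scaffold. In control replicate 1 the strongest lay within ACYP2, 116299 bp from a gene end, with 13 tags.

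For genes with a divergent transcript, which marks the side of the transcription start, gene-end peaks after si-Uc003xsl.1 lay almost always on that side. In replicate 1, 52 genes had a peak at the end facing the divergent transcript alone and 2 at the other end alone (96.3%, exact interval 87.3 to 99.5). In replicate 2 it was 56 against 2 (96.6%, interval 88.1 to 99.6). The gene-end peaks may therefore mark transcription start sites, a hypothesis whose test could have come out at 50%. Controls had 3 such genes in all, 0 against 2 and 1 against 0, too few for a comparison.

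Regions were shared between the si-Uc003xsl.1 lists and hardly at all with controls. An even spread of peaks is argued against by an overlap 14.2 times the mean of local placements. Those placements did not keep the share near gene ends (3.43% and 4.13% against 16.0% and 21.98%), so chance meeting at gene ends was not tested. Genes with a gene-end peak in both libraries numbered 133 against 69.6 for independent lists. List length is argued against by the 0.148% that the equally long list of control replicate 1 shared with si-Uc003xsl.1 replicate 1. The other caller of control replicate 2 is argued against as the whole cause by the 0.0896% shared between control replicate 1 and si-Uc003xsl.1 replicate 2, which came from the same program. Low ChIP over input enrichment in control replicate 1 remains a candidate explanation, since its median false discovery rate was 100%. More NKRF on chromatin after the siRNA against the RNA cannot be told apart from it, because 0 peaks of control replicate 1 had a false discovery rate at or below the higher si-Uc003xsl.1 median of 30.8%.

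Peaks near gene ends made up a larger share after si-Uc003xsl.1. Replicate 2 had 0.588 times the filtered tags of control replicate 1 and a larger share. In each group, however, the library with fewer tags had the larger share, so that comparison alone cannot exclude depth. Replicate 1 and control replicate 1 had near equal depth, with 18890698 and 19335431 filtered tags. Their shares of 16.0% and 1.36% argue against depth for this pair. Signal from open chromatin at any active gene could not be decided, since 7 and 2 peaks of replicates 1 and 2 lay near tRNA genes on chromosomes against highest placements of 7 and 5. The outcome written down in advance as speaking against it was met, but within counting error (exact Poisson upper limits 14.4 and 7.22). A change in NKRF binding itself stays open, as for the shared regions, and was not tested separately.

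Peaks at the smallest tag count differed in place from those with 10 or more tags, of which 42.8% and 48.5% lay near gene ends in si-Uc003xsl.1 replicates 1 and 2. Of 1477 6-tag peaks of replicate 2, 0 overlapped a 6-tag peak of replicate 1, within the range of local placements (mean 0.5, at most 2). Some overlapped a peak with more tags there, and without peaks at the smallest tag count the shared regions numbered 150 against 155. Among peaks with 10 or more tags, 129 of 1658 overlapped (highest placement 12). Chance clusters of tags were not decided: 2.69% and 2.57% of the 6-tag peaks of si-Uc003xsl.1 replicates 1 and 2 lay near gene ends, within the range of local placements, but 0.967% in control replicate 1 (interval 0.716 to 1.28) lay below its lowest placement of 1.11%. DNA copy number may set where such peaks fall, since their number per 5-Mb bin correlated between control replicate 1 and the si-Uc003xsl.1 libraries with Spearman's rho of 0.427 and 0.594 over 619 bins (0.325 and 0.537 over 582 bins with a gene and a peak). The other pairs gave 0.322 (0.217 over 582 bins) within the si-Uc003xsl.1 pair and, with all peaks of control replicate 2, 0.482 (0.422) with control replicate 1, 0.266 (0.169) with si-Uc003xsl.1 replicate 1 and 0.467 (0.409) with replicate 2, and mappability would act in the same way. Copy number would be shared by all libraries of this cell line. Yet the correlation within the si-Uc003xsl.1 pair was lower than that of control replicate 1 with either of its libraries. These correlations therefore do not single out copy number. No biological explanation was tested for these peaks.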
